A study of Canis lupus familiaris with 9 samples.

How the data were processed

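Muscle RNA of 9 dogs, 5 fed ad libitum and 4 fed to hold body weight, was measured on 1 Affymetrix canine array each. Total RNA was extracted with Trizol and biotin-labelled cRNA was made with a 3' amplification kit, per the labels' protocols. The deposited values were made with GCRMA, per the submitters' processing notes, which give no version. GCRMA corrects each probe for background from its sequence, normalizes arrays to a common distribution by quantiles and summarises the probes of a set to 1 value. The log base of the deposited values is not given in the sources used here and was taken as log2 from their range, 0.652 to 16.6, which GCRMA output on that scale has. Quantile normalization gives all arrays nearly the same distribution, so a shift of most transcripts in 1 group would not appear. GCRMA also leaves low values spread over several log2 units, so differences of probe sets near background are uncertain in size.

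Each dog's group was taken from its treatment label, and its replicate number is the animal number in the labels. The labels name no batch, scan date or litter, so none was tested. No further filtering by the authors is given in the sources used here. Of the 43035 probe sets, 111 control probe sets were left out and the 18394 with a log2 value above 4 on at least 4 arrays were tested. Gene names came from the platform annotation of 2016: 29264 probe sets had 1 symbol, 439 had several and were not named, and 13332 are unnamed here. Of the former, 27690 had an Entrez gene ID found in the gene table of assembly UU_Cfam_GSD_1.0, used for names only, and 0 symbols changed. Of the tested probe sets, 13887 had 1 symbol and 4507 did not.

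Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, two-sided, no covariate) on the deposited log2 values of all 9 arrays, and adjusted over the tested probe sets by the Benjamini-Hochberg method. The threshold was an adjusted p under 0.05. Values are given as mean ± SD over dogs, and log2 differences as ad libitum minus control with the standard error of the fit, which had 7 residual degrees of freedom and 2.32 prior degrees of freedom. Gene lists were tested with camera at its preset correlation of 0.01 over 7534 genes, each represented by the tested probe set with the highest mean over all arrays, and calls were repeated with an estimated correlation and with fry. Of 31 lists, 28 had the 4 measured genes needed. Neighbouring lists share few genes: the matrix and fibroblast lists share 2, and 5 other pairs share 1 each. Per-dog list means were compared with two-sided exact permutation tests over the 126 arrangements of the dogs, whose smallest p is 0.00794. The adjusted p of these tests is over the 28 lists.

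The groups, tests, lists, alternatives and rules for naming genes were fixed before the data were examined, except for a repeat of camera with an estimated correlation that is described with the alternatives' results. Genes were named by 3 rules. The first took the 12 genes per direction with an adjusted p under 0.05, filled up by the lowest unadjusted p where fewer passed. Since none passed, all 24 were taken by unadjusted p. The second was a panel of 28 genes of muscle metabolism, of which 23 were tested, each by its probe set with the highest mean. The third took up to 4 members per list with the lowest p. FN1, MMP2, RBP4, PDGFRA, NFKB1, PSMD11, PSMD7 and GPD1, named in addition as members of their lists, were chosen after their values were seen.

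The alternatives were no filter, a filter at log2 6, a floor at log2 4, cyclic loess, centring each array on its median, an intensity trend or robust estimation in eBayes, array weights, the mean of the adipocyte or the slow fibre list as a covariate, and leaving out each dog in turn. Further alternatives were 1 probe set per gene, an adjusted p under 0.10, an unmoderated test, the mean over all probe sets of a gene, and other probe sets of the named genes. The limma and camera steps were tested on simulated data with the means and spreads of this comparison, 18394 probe sets and 200 changed in each of 5 runs. At an adjusted p under 0.05 limma recovered 50.1% of probe sets changed by a log2 difference of 1, 88.1% at 2 and 95.2% at 3, and called 49 of 90970 unchanged ones. In these simulations probe sets varied independently, and the 200 changed ones eased the adjusted threshold for each other. With fewer changed probe sets the recovered shares could be lower, so they do not show what would have been found in these dogs. Camera called 15 of 15 lists shifted by a log2 difference of 1 with the preset correlation, 14 of 15 with an estimated correlation, and 0 of 125 unshifted lists. Since the simulated genes varied independently, the last count does not show how often camera calls unshifted lists whose genes vary together.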

Results

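Skeletal muscle of 9 intact female beagles, 4 years old, was profiled on an Affymetrix canine expression array after 24 weeks of a feeding trial. The dogs had been assigned at random to eat ad libitum, that is without restriction, or to receive the amount that kept their body weight at baseline. The ad libitum group held 5 dogs (animals 2, 5, 6, 7 and 8) and the control group held 4 dogs (animals 1, 3, 4 and 9), each a separate animal with 1 array. Muscle was taken after an overnight fast. Each array gave a GCRMA value for 43035 probe sets, from 0.652 to 16.6 on what was taken as the log2 scale, and 18394 probe sets were tested. Array pairs correlated at r = 0.976 to 0.994 across probe sets, and 0 of the 36 pairs held identical values. The number of arrays limits the precision: the median standard error of a log2 difference was 0.197. Genes are named by symbol. Chromosome positions are not given because no genome build belongs to these probe set values.

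The comparison asked which transcripts of skeletal muscle differ between dogs fed without restriction and dogs held at constant body weight. The transcripts with the smallest p among those lower in ad libitum muscle were CISH and SOCS2, members of the suppressor of cytokine signalling family, which act as feedback inhibitors of cytokine and growth hormone receptors. CISH averaged 2.57 ± 1.08 (SD, n = 5) in ad libitum and 6.97 ± 0.55 (SD, n = 4) in control dogs, a log2 difference of -4.40 (SE 0.53). SOCS2 averaged 5.38 ± 0.88 against 7.68 ± 0.23, a log2 difference of -2.31 (SE 0.41). Among the transcripts higher in ad libitum muscle were LEP, the adipocyte hormone leptin, with a log2 difference of 2.41 (SE 0.57), and NNAT, neuronatin, with 2.16 (SE 0.48). For CISH, SOCS2, LEP and NNAT, 5 of 5 ad libitum dogs lay beyond all 4 control dogs. With limma and Benjamini-Hochberg adjustment over the 18394 probe sets, however, 0 probe sets passed an adjusted p of 0.05 and 0 passed 0.10. The lowest adjusted p was 0.230, for CISH, and that of SOCS2, LEP and NNAT was 0.796.

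Without adjustment, limma gave 1088 probe sets with p under 0.05, of which 682 were higher and 406 lower in ad libitum dogs, where chance alone gives 919.7. The groups did not overlap for 264 probe sets (136 with all ad libitum dogs above and 128 with all below), or 1.44% of those tested, and chance gives 1.59%. The 1088 became 683 without ad libitum dog 5 and 2149 without ad libitum dog 7, and without dog 7 the number at an adjusted p under 0.10 was 59. With values below log2 4 raised to 4, CISH alone passed, with a difference of -2.97 and an adjusted p of 0.00461 (limma), since all 5 ad libitum arrays held CISH below that level and the floor gave them 1 value.

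**Figure D1:**
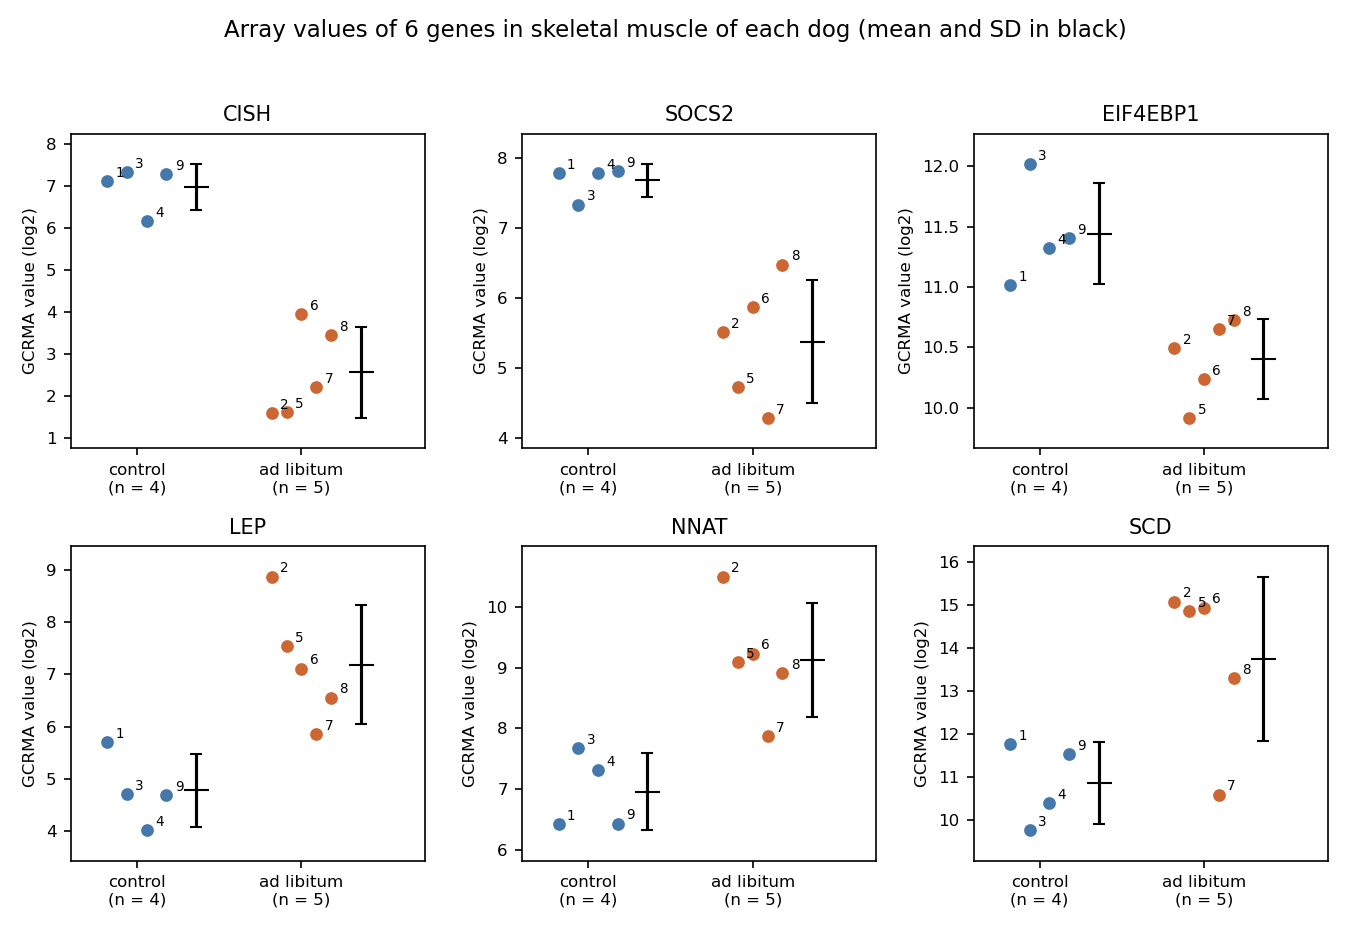
GCRMA values (log2, vertical axes) of 6 genes in each dog, with control dogs in blue and ad libitum dogs in orange, the animal number beside each point, and the mean and SD of each group in black. CISH lies between 1.60 and 3.96 in ad libitum dogs and between 6.16 and 7.32 in control dogs, and ad libitum dog 7 lies among the control dogs for SCD but not for CISH or SOCS2.

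None of the 24 transcripts with the smallest p in each direction passed the test, so their differences are given as values. Of the 12 that were lower in ad libitum muscle, EIF4EBP1, a repressor of cap-dependent translation, stood at 10.4 ± 0.329 (SD, n = 5) against 11.4 ± 0.419 (SD, n = 4), a log2 difference of -1.04 (SE 0.23). The carnitine transporter SLC22A5 differed by -1.40 (SE 0.31), the cationic amino acid transporter SLC7A2 by -0.94 (SE 0.21), and the splicing regulator MBNL1 by -1.08 (SE 0.23). The log2 differences of NRBF2, which takes part in autophagy, and of CCRL2, a chemokine receptor-like protein, were -1.12 and -1.38. Those of FLT1, a receptor of vascular endothelial growth factor, and of CCNE2, a cyclin, were -0.67 and -0.58, and those of MYNN and ZC3HC1 were -0.83 and -0.50. Of the 12 that were higher, TAGLN2, an actin-binding protein, differed by 1.70 (SE 0.42), SLC25A5, an ADP/ATP carrier of the inner mitochondrial membrane, by 0.86 (SE 0.21), and BLVRA, biliverdin reductase, by 0.72 (SE 0.15). DYNLT2B differed by 1.17, TPST1 by 0.91, TMEM17 by 0.80, PRAF2 by 0.78, RABEPK by 0.68, LOC477699 by 0.65 and CIB1 by 0.61. Each of these genes is given by its probe set with the lowest p. Another probe set of LOC477699 had a difference of -0.18, and others of TMEM17, PRAF2 and RABEPK had 0.012, 0.012 and 0.031. Over 6 probe sets MBNL1 ran from -1.08 to -0.28, and over 3 probe sets NNAT ran from 1.07 to 2.16.

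The extracellular matrix list had the largest difference of the 28 gene lists tested. All 30 measured members had higher means in ad libitum muscle, with a mean log2 difference of 1.54, and 0 passed the single-gene test, either over all probe sets or adjusted over the list alone, while 16 had an unadjusted limma p under 0.05. COL3A1 and COL1A1, fibrillar collagens, averaged 11.3 ± 2.24 and 12.6 ± 2.08 (SD, n = 5) in ad libitum dogs against 7.98 ± 0.557 and 9.56 ± 0.844 (SD, n = 4) in control dogs, log2 differences of 3.27 (SE 1.01) and 3.02 (SE 0.97). Fibronectin, FN1, differed by 2.52, the gelatinase MMP2 by 2.10 and the proteoglycan FMOD by 2.43. FMOD averaged 3.70 in control dogs, below the filter at log2 4, so the size of its difference is uncertain. The list mean stood at 9.14 ± 1.30 (SD, n = 5) against 7.60 ± 0.512 (SD, n = 4), with 4 of 5 ad libitum dogs above the control mean and an exact permutation p of 0.0635. Camera with its preset correlation called the list (adjusted p = 3.98e-16), and the call was lost with an estimated correlation (adjusted p = 0.577 with an estimated correlation of the genes). Markers of other cell types moved with it, and with the mean of the adipocyte markers as a covariate the matrix difference was 0.42 (adjusted p = 0.0617).

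Markers of adipocytes, macrophages and fibroblasts were also higher in ad libitum muscle. The adipocyte list had a mean log2 difference of 1.06, with 13 of 14 members higher. Over all probe sets 0 members passed, and adjusted over the list alone 1 did, LEP (adjusted p = 0.0284, limma). PCK1, an enzyme of glyceroneogenesis, differed by 3.81 (SE 1.35), hormone-sensitive lipase, LIPE, by 1.22 (SE 0.40), and RBP4 by 1.90 (SE 0.87), while ADIPOQ, adiponectin, differed by 0.36 (SE 0.72) and FABP4 by 0.70 (SE 0.36). Another probe set of PCK1 had 1.28, and the difference of 3.81 fell to as little as 2.58 when 1 dog was left out. Control dogs 4 and 3 held PCK1 at 1.91 and 4.38, below or near the filter at log2 4. The macrophage list had a mean log2 difference of 1.24 with 11 of 11 members higher, among them the lysosomal protease CTSS with 1.89 (SE 0.78), LAPTM5 with 2.05 (SE 0.86) and the scavenger receptor CD163 with 1.42 (SE 0.60). CD163 averaged 3.83 in control dogs, also below that filter, so the size of its difference is uncertain. The list of fibroblasts and fibro-adipogenic progenitors had a mean log2 difference of 0.82 with 15 of 16 members higher, among them S100A4 with 1.74 and THY1 with 1.87, and PDGFRA had 0.12. No macrophage or fibroblast marker passed the single-gene test, over all probe sets or adjusted over the list alone. Camera with the preset correlation called the adipocyte list (adjusted p = 3.8e-05), the macrophage list (adjusted p = 1.83e-05) and the fibroblast list (adjusted p = 0.000114). None held, with adjusted p = 0.577 for each with an estimated correlation, and exact permutation of the list means gave p = 0.0714, 0.0873 and 0.135. Without ad libitum dog 5 the macrophage difference was 0.77, and camera's call stayed with the preset correlation (adjusted p = 5.15e-05) but not with an estimated correlation (adjusted p = 0.449). With the adipocyte covariate the macrophage difference was 0.55 (adjusted p = 0.115) and the fibroblast difference -0.0018.

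**Figure D2:**
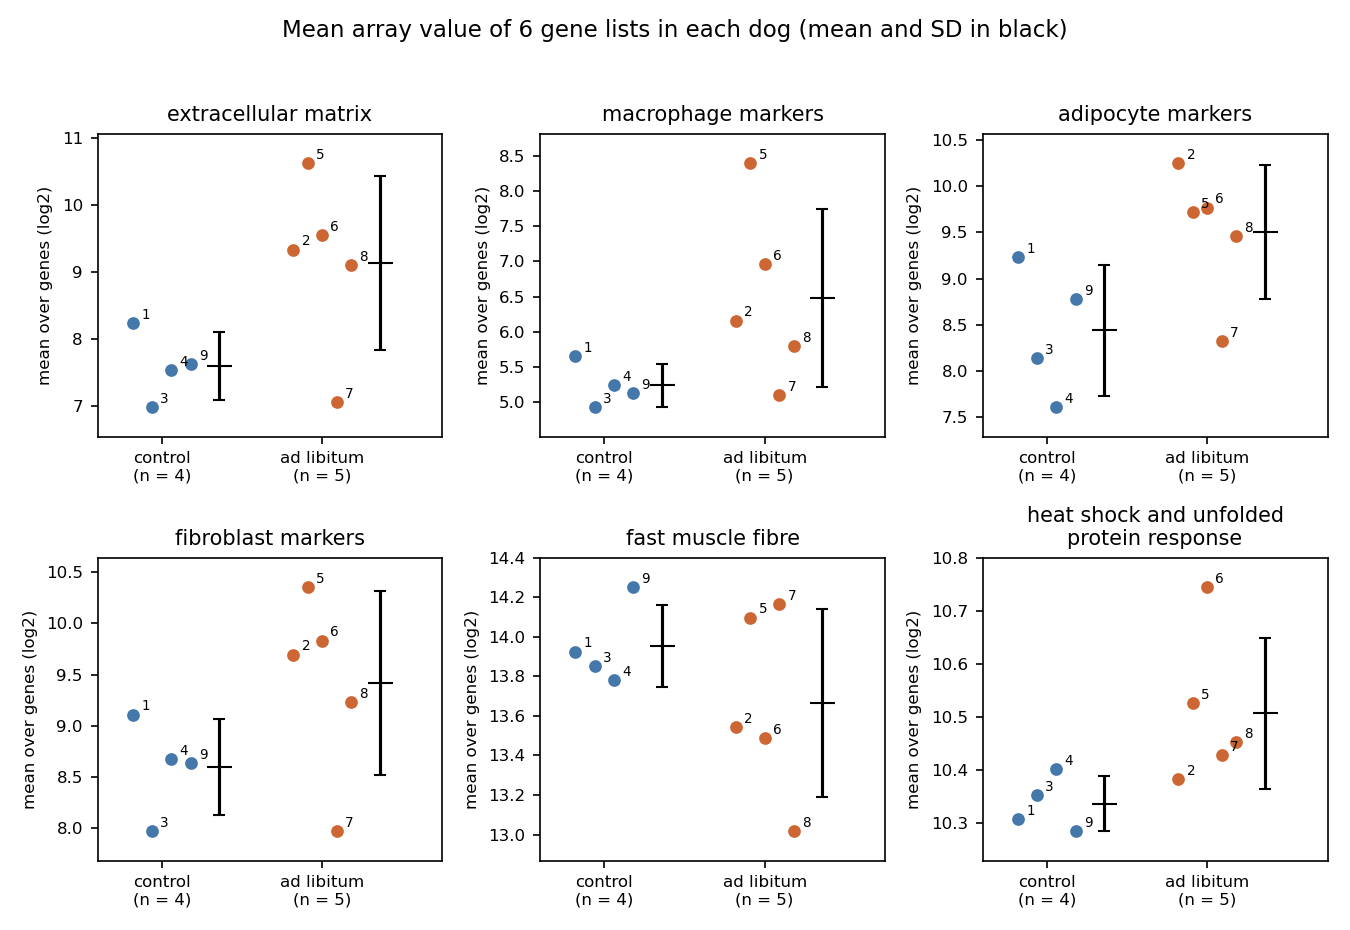
Mean value (log2, vertical axes) over the measured genes of 6 lists in each dog, with control dogs in blue and ad libitum dogs in orange, the animal number beside each point, and the mean and SD of each group in black. In the matrix, macrophage, adipocyte and fibroblast lists, 4 of 5 ad libitum dogs lie above the control mean and ad libitum dog 7 lies below it.

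Endothelial and smooth muscle lists had mean differences near 0. The endothelial list had a mean log2 difference of -0.039, with 7 members higher and 8 lower (adjusted p = 0.493, camera), and FLT1 and KDR, the receptors of vascular endothelial growth factor, at -0.67 and -0.41. Smooth muscle and pericyte markers differed by 0.067 (adjusted p = 0.722, camera), with SMTN, smoothelin, at 0.55 (SE 0.20). Camera called both lower with the adipocyte covariate, endothelial markers at -0.21 (adjusted p = 0.00782) and smooth muscle and pericyte markers at -0.18 (adjusted p = 0.0176), and neither call held with an estimated correlation (adjusted p = 0.464 for each). Of the lists with too few measured members for a test, the lymphocyte list kept 1 gene, JCHAIN, with a log2 difference of -0.053. The nerve and Schwann cell list kept 3, PMP22, MAL and S100B, with 0.78, 1.50 and 0.61. The red blood cell and platelet list kept 3, GYPC, PPBP and ALAS2, with -0.026, -0.30 and -0.19. RNA quality, read from the GAPDH control probe sets as the 3' minus 5' value, was 2.21 ± 0.0676 (SD, n = 5) in ad libitum and 2.09 ± 0.107 (SD, n = 4) in control dogs (exact permutation p = 0.0714).

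Contractile genes of fast fibres had lower means in ad libitum muscle. The fast muscle fibre list differed by a mean log2 of -0.29, with 15 of 15 members lower and 0 past the single-gene test over all probe sets or adjusted over the list alone. Its mean stood at 13.7 ± 0.476 (SD, n = 5) against 14.0 ± 0.208 (SD, n = 4), with an exact permutation p of 0.294. ACTN3, the alpha-actinin of fast fibres, differed by -1.06 (SE 0.76) and by -0.37 without ad libitum dog 8, the fast myosin heavy chain MYH1 by -1.01 (SE 1.05) and MYBPC2 by -0.49 (SE 0.31). Without ad libitum dog 8 MYH1 differed by -0.41 and MYBPC2 by -0.28, and without ad libitum dog 6 or 7 MYH1 differed by -0.48 or -1.61. The slow fibre list differed by 0.061 (adjusted p = 0.235, camera), with the slow myosin heavy chain MYH7 at 0.16 (SE 0.12), and the slow muscle fibre list was called with no filter (adjusted p = 0.00346) and with array weights (0.20, adjusted p = 0.031). MYH7 differed by 0.096 to 0.23 with a dog left out, and by up to 0.38 over its 4 probe sets. The glycolysis and glycogen metabolism genes differed by a mean log2 of -0.14, with 18 of 24 members lower, among them PKM, pyruvate kinase, at -0.61 (SE 0.28), TPI1 at -0.29 and PGAM2 at -0.33. Camera with the preset correlation called the fast fibre list (adjusted p = 0.00816) and the glycolysis list (adjusted p = 0.00883), each lost at adjusted p = 0.577 with an estimated correlation. The fast fibre call also ended without control dog 9 (-0.19, adjusted p = 0.0658) and without ad libitum dog 8 (-0.13, adjusted p = 0.158). The glycolysis call ended without either of these dogs or ad libitum dog 2, at differences between -0.098 and -0.080, and with no filter on low values (adjusted p = 0.0952). It ended with the adipocyte covariate too, and the direction of the glycolysis and glycogen metabolism list turned (0.016, adjusted p = 0.568), while without ad libitum dog 7 the difference was -0.24.

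The lipid storage and fasting response lists had higher means in ad libitum muscle, with members in both directions, and were called by camera only under other settings than the planned one. DGAT2, which makes triglyceride, averaged 9.55 ± 1.69 (SD, n = 5) against 6.77 ± 0.418 (SD, n = 4), a log2 difference of 2.77 (SE 0.77), and SCD, stearoyl-CoA desaturase, differed by 2.90 (SE 0.92). AGPAT2 and MGLL of the lipid uptake, storage and lipolysis list differed by 0.76 and 0.82. The mean log2 difference of that list was 0.30 (exact permutation p = 0.0317 and adjusted p = 0.333, camera adjusted p = 0.171), with 11 of 18 members higher and 5 of 5 ad libitum dogs above the control mean. The list of fasting-responsive PPAR targets differed by 0.31 (exact permutation p = 0.0397 and adjusted p = 0.333, camera adjusted p = 0.0737), with 8 members higher and 6 lower. Higher were ANGPTL4, an inhibitor of lipoprotein lipase, at 1.43 (SE 0.41), CPT1A at 0.74 (SE 0.22) and PLIN2 at 0.55 (SE 0.23). PDK4 and UCP3 of the same list differed by 0.23 (SE 0.22) and 0.61 (SE 0.46), and PPARGC1A by -0.28, but without control dog 4 PDK4 differed by 0.011 and UCP3 by 0.33, and without ad libitum dog 7 UCP3 differed by 0.28. Camera called the fasting-responsive PPAR targets without control dog 1 (0.41, adjusted p = 0.0331), ad libitum dog 5 (0.35, adjusted p = 0.0204) or ad libitum dog 6 (0.35, adjusted p = 0.0405), and the lipid uptake, storage and lipolysis list without ad libitum dog 5 (0.37, adjusted p = 0.03). With an estimated correlation none of these calls held (adjusted p = 0.449 to 0.656), and without control dog 4 the fasting-responsive PPAR targets differed by 0.17. With all 9 dogs the fasting-responsive PPAR targets were called with no filter (adjusted p = 0.00625), with the filter at log2 6 (adjusted p = 0.048) and with the slow fibre covariate (adjusted p = 0.0314). The lipid uptake, storage and lipolysis list was called with no filter (adjusted p = 0.013) and with the adipocyte covariate (0.32, adjusted p = 0.0176, and 0.464 with an estimated correlation). Fatty acid synthesis and desaturation genes differed by 0.53 (camera adjusted p = 0.171), with ACLY at 1.27 (SE 0.56) and FASN at 0.62 (SE 1.13), and the fatty acid synthesis and desaturation list was called with no filter (adjusted p = 0.0297) and with the filter at log2 6 (adjusted p = 0.048). With the adipocyte covariate the SCD difference was 0.83, that of FASN -2.16 and that of the fatty acid synthesis list -0.18. The lipoprotein lipase gene LPL differed by -0.30 (SE 0.21) and the fatty acid transporter CD36 by 0.18 (SE 0.27). When 1 dog was left out LPL ran from -0.46 to -0.21 and CD36 from 0.044, without ad libitum dog 7, to 0.36. No member of these lists passed the single-gene test, over all probe sets or adjusted over the list alone.

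Oxidative metabolism showed small differences in both directions, and its lists were called by camera only under other settings than the planned one. The 21 fatty acid oxidation genes differed by a mean log2 of 0.10 (adjusted p = 0.171, camera), with HADHB at 0.29, MLYCD at 0.34 and ECI1 at 0.47, and CPT1B, the muscle carnitine palmitoyltransferase, had 0.28 (SE 0.29), or 0.11 without ad libitum dog 8. Without ad libitum dog 5 the fatty acid oxidation list was called (0.18, adjusted p = 0.0098), though not with an estimated correlation (adjusted p = 0.449), and the difference was 0.048 without control dog 3 and 0.059 without ad libitum dog 7. It was also called with the adipocyte covariate (0.17, adjusted p = 0.0398, and 0.622 with an estimated correlation) and with no filter on low values (adjusted p = 0.00346). The 46 oxidative phosphorylation genes differed by 0.033 (adjusted p = 0.518, camera), with single genes between -0.16 and 0.34, and the oxidative phosphorylation list was called with no filter (adjusted p = 0.00552). The tricarboxylic acid cycle list differed by -0.095 (adjusted p = 0.0648, camera), with 16 of 18 members lower and FH, fumarase, at -0.27 (SE 0.12). The mitochondrial biogenesis list differed by -0.25 (adjusted p = 0.0644, camera), with 11 of 13 members lower. The mitochondrial biogenesis list differed by -0.0079 and the tricarboxylic acid cycle list by -0.00027 with the adipocyte covariate. Without ad libitum dog 7 both were called, at -0.33 (adjusted p = 0.0333) for mitochondrial biogenesis and -0.16 (adjusted p = 0.0166) for the tricarboxylic acid cycle, as was mitochondrial biogenesis without control dog 1 (-0.31, adjusted p = 0.0464) and the tricarboxylic acid cycle without control dog 3 (-0.17, adjusted p = 0.0014). With an estimated correlation none of these calls held (adjusted p = 0.391 to 0.660). Both lists were also called with the filter at log2 6, mitochondrial biogenesis at adjusted p = 0.048 and the tricarboxylic acid cycle at adjusted p = 0.0436, and with array weights, at adjusted p = 0.031 and adjusted p = 0.0112. Other dogs had the opposite effect, with mitochondrial biogenesis at -0.14 without ad libitum dog 2 and the tricarboxylic acid cycle at -0.052 without control dog 9. MFN2, which fuses mitochondria, averaged 9.18 ± 0.199 (SD, n = 5) against 10.1 ± 0.798 (SD, n = 4) and lay below all control dogs in 5 of 5 ad libitum dogs, a log2 difference of -0.94 (SE 0.33), and PPARGC1A had -0.28 (SE 0.19). Cholesterol synthesis genes differed by 0.014 (adjusted p = 0.757, camera), with FDPS and SC5D at -0.33 and -0.50 and MSMO1 at 0.42. For that list the sign of camera's direction, which was down, differed from that of the mean.

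Genes of insulin signalling and of growth control were mixed. The insulin signalling and glucose uptake list differed by -0.067 (adjusted p = 0.389, camera), with IRS1 at -0.35 (SE 0.19), TBC1D4 at -0.61 (SE 0.35) and SLC2A4, the insulin-regulated glucose transporter, at 0.069 (SE 0.33), and the hexokinase HK2 had 0.032 (SE 0.26). When 1 dog was left out the insulin list differed by between -0.14 and -0.0058. In the myogenic and growth control list 0 members passed over all probe sets, and adjusted over the list alone 2 passed, both lower: EIF4EBP1 and ACVR2B, an activin and myostatin receptor, at -0.70 (SE 0.19), with a lowest adjusted p of 0.0266 (limma). IGF1R, the receptor of insulin-like growth factor 1, differed by -0.77 (SE 0.26) and its ligand IGF1 by 0.96 (SE 0.66). IGF1 differed by 0.50 without control dog 4, by 0.54 without ad libitum dog 5 and by -0.27 with the adipocyte covariate. The myogenic and growth control list had a mean log2 difference of 0.026, a median of -0.048 and a downward camera direction (adjusted p = 0.171). It was called with the adipocyte covariate (-0.13, adjusted p = 0.0275), but not with an estimated correlation (adjusted p = 0.464). Of the immediate early genes 10 were higher and 4 lower, and the 4 with the smallest p were FOSL2 at -1.39 (SE 0.43), MYC at -1.41 (SE 0.53) and DUSP1 at -0.80 (SE 0.30), all lower, and IER2 at 1.03 (SE 0.36). The mean of the immediate early genes was -0.027, their median 0.12 and camera's direction was down (adjusted p = 0.876). With the adipocyte covariate the mean of the immediate early genes was -0.67 (adjusted p = 1.14e-05, camera), a call that was lost with an estimated correlation (adjusted p = 0.160). The circadian list differed by -0.077 with a median of 0.053 (adjusted p = 0.493, camera), and NFIL3 had -0.73 (SE 0.33). The circadian difference was -0.014 without control dog 4 and -0.14 without control dog 9.

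Genes of protein folding had higher means in ad libitum muscle. In the heat shock and unfolded protein response list 23 of 29 members were higher and 0 passed the single-gene test, over all probe sets or adjusted over the list alone. PDIA3, a disulphide isomerase of the endoplasmic reticulum, differed by 0.54 (SE 0.15), the stress-induced transcription factor DDIT3 by 0.86 (SE 0.24), HSPA5, the main chaperone of the endoplasmic reticulum, by 0.67 (SE 0.24) and the small heat shock protein HSPB7 by 0.72 (SE 0.23). The list mean differed by 0.17 and lay above the control mean in 5 of 5 ad libitum dogs (exact permutation p = 0.0397, adjusted p = 0.333). Camera with the preset correlation called it (adjusted p = 0.019), and the call was lost at adjusted p = 0.577 with an estimated correlation, without control dog 9 (0.15, adjusted p = 0.0658) and without ad libitum dog 6 (0.11, adjusted p = 0.237). Antioxidant defence genes differed by 0.14 (exact permutation p = 0.0476 and adjusted p = 0.333, camera adjusted p = 0.108), with TXN, thioredoxin, at 0.60 (SE 0.26), its reductase TXNRD1 at 0.59 (SE 0.24), GPX1 at 0.53 (SE 0.22), and GPX3 at -0.88 (SE 0.77). GPX3 differed by -0.13 without control dog 3. Camera called the antioxidant defence list without ad libitum dog 8 (0.17, adjusted p = 0.0408), but not with an estimated correlation (adjusted p = 0.608), and with no filter (adjusted p = 0.00346).

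Protein turnover lists had differences near 0. In the list of proteasome and ubiquitin ligases of muscle atrophy, 23 of 32 members were higher, with a mean log2 difference of 0.062. The subunit PSMA5 differed by 0.32 (SE 0.11) and PSMA2 by 0.26 (SE 0.14), or 0.13 without control dog 3, while FBXO32, the ubiquitin ligase atrogin-1, differed by -0.81 (SE 0.34) and TRIM63, the ligase MuRF1, by -0.061 (SE 0.19). The subunits PSMD11 and PSMD7 were lower, at -0.17 and -0.10. The cytosolic ribosomal proteins differed by -0.067, with 29 of 37 members lower and RPL7A at -0.23 (SE 0.10). No member of either list passed the single-gene test. Camera with the preset correlation called the proteasome list (adjusted p = 0.0357) and the ribosomal list (adjusted p = 0.0269). Both calls were lost, at adjusted p = 0.577 for the proteasome list and adjusted p = 0.646 for the ribosomal list with an estimated correlation. The proteasome call also ended without control dog 1 or 3 or ad libitum dog 6 or 7 (0.016 to 0.052), with a stricter filter (adjusted p = 0.0664), with arrays centred on their median (0.020) and with array weights (0.023), and without control dog 9 the difference was 0.11. The ribosomal call also ended without control dog 1 or 9 or ad libitum dog 6 or 7 (-0.066 to -0.023), with no filter (adjusted p = 0.178) and with cyclic loess (adjusted p = 0.0533), and without ad libitum dog 8 the difference was -0.10. Both stayed called, at larger differences, with the adipocyte covariate: cytosolic ribosomal proteins at -0.15 (adjusted p = 1.28e-06) and the proteasome and ubiquitin ligases of muscle atrophy at 0.14 (adjusted p = 0.0029), each lost with an estimated correlation (adjusted p = 0.464). The autophagy list differed by 0.065 (adjusted p = 0.493, camera), with FOXO3 at -0.38 (SE 0.20), and was called with no filter (adjusted p = 0.048). Its list difference ranged from 0.024 to 0.093 when 1 dog was left out.

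The inflammatory and interferon lists had higher means in ad libitum muscle and were called by camera only under other settings than the planned one. The list of inflammatory cytokines, chemokines and acute phase genes differed by 0.48 (adjusted p = 0.171, camera), with 8 members higher and 4 lower. Higher were the adhesion molecule VCAM1 at 1.34 (SE 0.43), CXCL14 at 1.95 (SE 0.96) and the monocyte chemokine CCL2 at 1.11 (SE 0.58), while NFKB1 had -0.20. The interferon response list differed by 0.25 (adjusted p = 0.0648, camera), with 6 of 7 members higher and OAS2 at 0.67 (SE 0.44). The differences shrank to 0.021 for inflammatory cytokines, chemokines and acute phase genes and 0.038 for the interferon response with the adipocyte covariate, and the interferon response difference was 0.12 without ad libitum dog 5. Camera called both lists without control dog 1, at 0.64 (adjusted p = 0.0464) for the inflammatory list and 0.32 (adjusted p = 0.0352) for the interferon response list, and without ad libitum dog 7, at 0.73 (adjusted p = 0.0166) and 0.34 (adjusted p = 0.0357). The interferon response list was also called without ad libitum dog 6 (0.33, adjusted p = 0.0219). With an estimated correlation none of these calls held (adjusted p = 0.345 to 0.656). With all 9 dogs both were called with no filter, the inflammatory cytokines, chemokines and acute phase genes at adjusted p = 0.0107 and the interferon response at adjusted p = 0.00466. The former were also called with the filter at log2 6 (adjusted p = 0.048), and the latter with the mean over all probe sets of a gene (adjusted p = 0.0315). The cytokines IL6 and TNF, and also SREBF1, IRS2 and the myostatin gene MSTN, stayed below the level needed for testing.

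Across the 28 lists, camera with its preset correlation called 9, of which 6 were higher and 3 lower in ad libitum muscle, and 5 without control dog 9. With no filter it called 17, and 29.9% of probe sets then had a positive difference, against 48.4% of those tested. With an estimated correlation 0 lists were called, over the 9 dogs or without any 1 of them, the lowest p over the 9 dogs being 0.0784 before and 0.577 after adjustment. The rotation test fry, which asks whether the genes of a list move 1 way on balance, called 0 (lowest p 0.0633 before and 0.543 after adjustment). Exact permutation of the per-dog list means gave p under 0.05 for 4 lists and 0 after adjustment (lowest adjusted p 0.333). Without ad libitum dog 7 there were 5 lists with p under 0.05, and without any 1 of the other dogs 0 or 1.

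**Figure D3:**
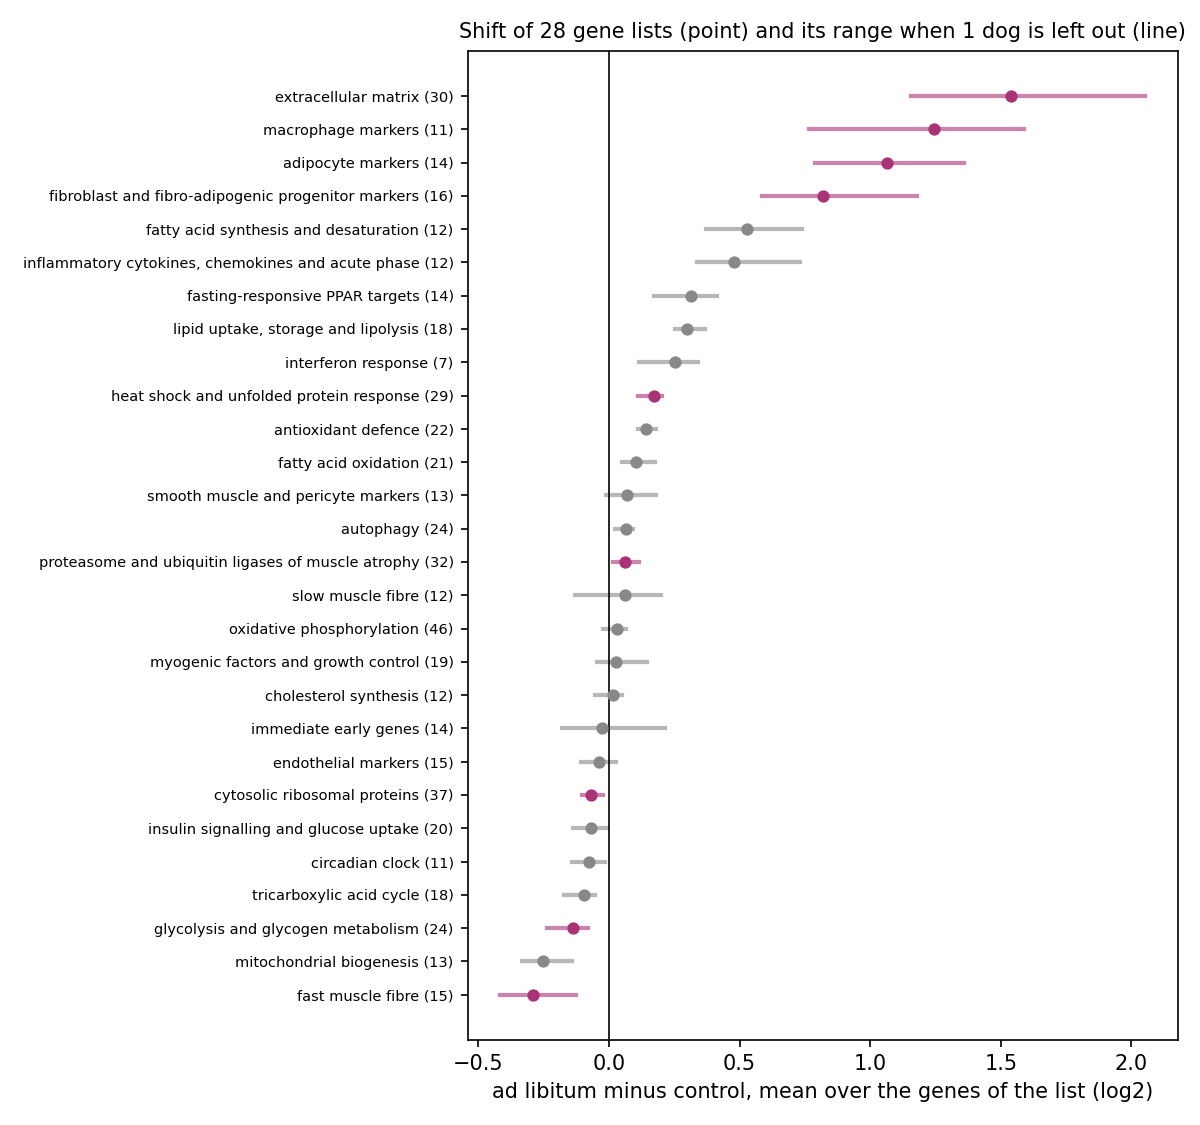
Mean log2 difference between ad libitum and control dogs (horizontal axis) for each of 28 gene lists, with the number of measured genes in parentheses. Points give the value over 9 dogs and lines its range when 1 dog was left out, and the 9 lists called by camera with the preset correlation are in purple, of which 0 were called with an estimated correlation. The extracellular matrix list lies at 1.54, and its range runs from 1.16 to 2.05.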

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

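All tests of explanations in this part were chosen only after the results they bear on had been seen. Of 148 groups of values checked for a dog far from the rest of its group, 7 passed Dixon's 95% value, where chance gives about 1 in 20, or 7.4.

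Ad libitum dog 7 stood apart in 4 of these. Its smooth muscle and pericyte mean of 8.64 lay below the next dog at 9.14 (Dixon's ratio 0.741), and its FABP4 value of 12.6 lay below 13.7 (ratio 0.739). Its UCP3 value of 14.0 lay above 12.4 (ratio 0.789), and its CCNE2 value of 4.79 lay above 4.56 (ratio 0.892). Control dog 4 was lowest of its group for the immediate early genes, at 7.40 against 7.98 (ratio 0.842), and for PDK4, at 13.7 against 14.5 (ratio 0.909). Control dog 3 was lowest for SOCS2, at 7.34 against 7.79 (ratio 0.953).

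The numbers of differing probe sets and lists were set against other splits of the 9 dogs into 5 and 4, with 100 splits drawn and the real one included. An unadjusted limma p under 0.05 was reached by 1088 probe sets in the real split, and 28 of the 100 splits gave as many, with 2602 the highest of the others. Camera with its preset correlation called 9 lists in the real split, and 29 of the 100 splits gave as many. The other splits called a median of 7 lists and at most 15, and 94 of the 100 splits called any. Chance cannot be excluded for the 1088 probe sets or the 9 lists. At an adjusted p under 0.05 the real split gave 0, a count that any split reaches (100 of 100), so this comparison decides nothing. One other split called 102 probe sets, and how far it shared the feeding groups was not examined. Only 8 of the 100 splits gave any, not far from what that level gives by chance. No structure among the dogs can be read from these counts.

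The first pattern is the higher extracellular matrix list. More fibroblasts alone, each with the same expression, would raise fibroblast markers about as much as matrix genes. The matrix difference exceeded that of 14 fibroblast markers by 0.78 (SE 0.22, exact permutation p = 0.0238, 1.58 against 0.81, with the 2 shared genes left out). Against the 6 fibroblast markers with a control mean no higher than that of the matrix list the excess was 0.92 (SE 0.29, exact permutation p = 0.0317). Neither excess excludes more fibroblasts alone, since the matrix list was taken up for having the largest difference of the 28 lists. More adipose tissue in the ad libitum samples also stays open, since the matrix difference exceeded that of the adipocyte markers by 0.47 with an SE of 0.45 (exact permutation p = 0.389). A response of muscle to feeding, which the design names, may contribute and was not tested apart from it.

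The second pattern is the lower CISH and SOCS2. Dilution of muscle RNA by other cells would lower 47 energy metabolism genes of middling intensity alike, if those cells hold little of these transcripts, which was not tested. The mean of these 47 genes, which were not picked for their difference, differed by -0.0072 (SE 0.13). That argues against such dilution as the whole cause of a mean difference of -2.64 for CISH and SOCS2 with values below log2 4 raised to 4. How far values near background contribute stays open: the floor brought CISH from -4.40 to -2.97 and moved no value of SOCS2, and both genes were picked for their low p. Lower STAT5 signalling, which both genes answer to, could be neither shown nor excluded. The mean of 6 other STAT5-responsive genes differed by 0.077 (SE 0.33, camera p = 0.978 with an estimated correlation), with 3 lower, MYC at -1.41 among them, and CCND2 at 1.10. A response to feeding is a hypothesis that remains open, since neither gene passed the adjusted test.

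The third pattern is the higher LEP. More adipocytes alone, each with the same expression, would raise the other adipocyte markers about as much. LEP exceeded the mean of 13 other markers by 1.45 (SE 0.32, exact permutation p = 0.00794, 2.41 against 0.96, larger in 5 of 5 ad libitum dogs than in any control dog). This does not argue against more adipocytes, since LEP was singled out of the list for its low p. PCK1 of the same list moved more, by 3.81, though by 1.28 in another probe set. Markers with a high level in control muscle, such as GPD1 and FABP4, could also hide a small share of adipocytes. More adipocytes and a higher LEP level per adipocyte both stay open, and the latter was not tested.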

How the results depend on the processing

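Camera with an estimated correlation, run also with each dog left out and with the adipocyte covariate, was chosen after the data were seen and called 0 lists each time (lowest adjusted p 0.160, with the covariate). For single genes, 688 of 698 values with 1 dog left out and 913 of 924 values under other settings kept direction and side of the threshold. For lists the numbers were 203 of 252 and 267 of 334. The single-gene counts show little about stability, since no gene passed in the main test and many were named for a low p in the same dogs. Robust estimation could not be run for camera, and covariate, weight, trend and robust settings give no permutation of dogs. No paired analysis was possible because the groups share no animal number. With no filter 29.9% of probe sets had a positive difference, with arrays centred on their median 40.5%, against 48.4% as deposited. The cause was not tested for any change below, except where fewer genes or dogs entered.

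Against 0 probe sets at an adjusted p under 0.05, 1 passed with the floor at log2 4 (CISH), and between 0 and 1 passed with a dog left out (1 without ad libitum dog 8, LOC489640, named after its value was seen). At an adjusted p under 0.10 there were 0, and 59 without ad libitum dog 7. The 1088 probe sets at an unadjusted p under 0.05 became 1865 with array weights, 472 with the adipocyte covariate, 683 without ad libitum dog 5 and 2149 without ad libitum dog 7. CISH differed by between -4.74 and -2.97 over its alternatives, with adjusted p of 0.00461 for the floor. These do not include the fits without a control dog. CISH lay above log2 4 in the 4 control dogs only, so leaving out any of them dropped it from the test. How far the adjusted p of CISH depends on single control dogs is thus not known. Each control value, from 6.16 to 7.32, lay above all ad libitum values, from 1.60 to 3.96. Against 9 lists called, 17 were called with no filter, 0 with an estimated correlation, 0 by fry and 5 to 12 with a dog left out. Against 4 lists with an exact permutation p under 0.05, there were 1 with cyclic loess, 0 with median centring, 1 with the mean over all probe sets of a gene, and 0 to 5 with a dog left out.

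Direction turned for the following results. With no filter the immediate early genes differed by 0.011. With the filter at log2 6 the insulin signalling list differed by 0.0040, the cholesterol synthesis list by -0.10 and the immediate early genes by 0.056. With median centring the myogenic list differed by -0.016, oxidative phosphorylation by -0.0097, cholesterol synthesis by -0.029 and HK2 by -0.011. With array weights oxidative phosphorylation differed by -0.016, cholesterol synthesis by -0.017, immediate early genes by 0.063 and SLC2A4 by -0.084. With the adipocyte covariate the fibroblast list differed by -0.0018, glycolysis and glycogen metabolism by 0.016, the myogenic list by -0.13, fatty acid synthesis by -0.18, insulin signalling by 0.070, smooth muscle by -0.18, FASN by -2.16, IGF1 by -0.27, ADIPOQ by -1.26 and FABP4 by -0.089. With the slow fibre covariate HK2 differed by -0.013. With the mean over all probe sets the immediate early genes differed by 0.046. Other probe sets gave -0.18 for LOC477699, -0.089 for SLC2A4 and 0.029 for TRIM63.

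With a dog left out, differences ran from -0.047 to 0.15 for the myogenic list, -0.13 to 0.20 for slow fibre, -0.11 to 0.028 for endothelial markers, -0.024 to 0.067 for oxidative phosphorylation, -0.013 to 0.18 for smooth muscle, -0.055 to 0.048 for cholesterol synthesis and -0.18 to 0.22 for immediate early genes. For single genes they ran from -0.16 to 0.28 for SLC2A4, -0.23 to 0.28 for HK2, -0.25 to 1.40 for FASN, -0.30 to 0.98 for ADIPOQ and -0.19 to 0.052 for TRIM63.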

Other observations

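All tests in this part were chosen after the results were seen. Matrix gene levels varied together with macrophage and adipocyte markers and with SCD across the 9 dogs. The matrix list mean correlated with SCD at Pearson's r = 0.941 (exact permutation p = 0.000234, adjusted p = 0.000937) and Spearman's rho = 0.917 (exact permutation p = 0.00131, adjusted p = 0.00525). With the macrophage list r was 0.932 (exact permutation p = 5.51e-06, adjusted p = 4.41e-05) and rho 0.983 (exact permutation p = 4.96e-05, adjusted p = 0.000397). With the adipocyte list r was 0.840 (exact permutation p = 0.00597, adjusted p = 0.0159) and rho 0.883 (exact permutation p = 0.00308, adjusted p = 0.0082). With LEP r was 0.793 (exact permutation p = 0.0118, adjusted p = 0.0236) and rho 0.767 (exact permutation p = 0.0214, adjusted p = 0.0428). Without the 2 dogs farthest from the median, ad libitum dogs 5 and 6, r was 0.951 for SCD, 0.969 for macrophage markers, 0.880 for adipocyte markers and 0.789 for LEP.

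For CISH and SOCS2, r with the matrix list was -0.619 (exact permutation p = 0.0743, adjusted p = 0.119) and -0.441 (exact permutation p = 0.231, adjusted p = 0.308), with rho of -0.600 (exact permutation p = 0.0968, adjusted p = 0.155) and -0.317 (exact permutation p = 0.41, adjusted p = 0.469). All 5 ad libitum values of CISH lay below log2 4, where sizes are uncertain, so its correlations cannot show whether CISH follows the matrix list. Without the same 2 dogs r was -0.483 and -0.113. The fast fibre list had r = -0.354 (exact permutation p = 0.353, adjusted p = 0.404) and rho = -0.333 (exact permutation p = 0.385, adjusted p = 0.469), and r was -0.738 without the 2 dogs. Oxidative phosphorylation had r = -0.068 (exact permutation p = 0.858, adjusted p = 0.858), rho = -0.083 (exact permutation p = 0.843, adjusted p = 0.843) and 0.068 without the 2 dogs. These 8 relations span both feeding groups, so a difference between groups enters each r. With the group means removed and dogs permuted within their groups, r with the matrix list was 0.900 for SCD (exact permutation p = 0.00486, adjusted p = 0.0389), 0.895 for macrophage markers (exact permutation p = 0.0146, adjusted p = 0.0583), 0.728 for adipocyte markers (exact permutation p = 0.0503, adjusted p = 0.134) and 0.608 for LEP (exact permutation p = 0.169, adjusted p = 0.338). It was -0.059 for CISH, 0.357 for SOCS2, -0.146 for the fast fibre list and -0.237 for oxidative phosphorylation (exact permutation p from 0.545 to 0.918). Whether these relations differ from each other was not tested.

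Ad libitum dog 7 had a matrix list mean of 7.07, a macrophage mean of 5.10 and an SCD value of 10.6, near control dog 3 with 6.99, 4.93 and 9.75. Its CISH and SOCS2 values were 2.22 and 4.29, where control dog 3 had 7.33 and 7.34. On the first principal component, which held 36.1% of the variance (exact permutation p = 0.0714 between groups), dog 7 lay at -38.6, control dog 3 at -39.6 and ad libitum dog 5 at 62.4.

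A hypothesis was that lower FBXO32 and EIF4EBP1, both induced by FOXO transcription factors, go with lower FOXO activity in ad libitum muscle. The mean of 16 other FOXO-responsive genes differed by -0.095 (SE 0.13, camera p = 0.337 with an estimated correlation), with 12 lower, among them CITED2 at -0.79 (SE 0.36), FBXO31 at -0.52 (SE 0.23) and FOXO3 at -0.38 (SE 0.20), while CDKN1A had 1.04 (SE 0.57). The test neither bears the hypothesis out nor excludes it.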
